A study of Mus musculus with 2 samples.

How the data were processed

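RNA was taken from the spinal cord of C57BL/6 mice at postnatal day 7, and 1 library was made for each of 2 groups, wild type (WT) and Olig1-Cre with floxed exon 3 of Secisbp2l (cKO). Per the labels' protocols, the tissue was kept in an RNA-preserving solution at low temperature, RNA was extracted with Trizol, and libraries were made with a VAHTS mRNA-seq V2 kit. The series' design text names an Illumina HiSeq instrument. The submitters' processing notes name CASAVA, Bowtie2 2.3.2 and the genome build GRCm38.p6, with no role for each. The counting tool, annotation release, read length and strand setting are not given in the sources used here.

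The authors deposited estimated counts, FPKM and TPM for 51826 genes and 128622 transcripts, per the file headers, with 1 column per library. Counts were the same in both files that list them. The deposited counts are whole numbers but are not tallies of reads. In 98.8% of WT and 98.7% of cKO transcripts with under 50 expected counts, the deposited count was the next whole number above a constant times FPKM times transcript length, within 0.1. The count of every gene was the sum of those of its transcripts. The constant times FPKM times length, which need not be a whole number, was also examined for genes with 1 transcript and few counts. This value gathered at even numbers: for 42.8% of 4056 such genes in WT and 40.3% of 4407 in cKO it lay within 0.2 of an even number, and for 13.8% and 14.9% within 0.2 of an odd number. One fragment was therefore taken as 2 counts, and intervals were computed on fragments. This was decided after the files had been examined, since the design written beforehand took 1 count as 1 read, and intervals on counts as deposited were run as an alternative. Rounding up each transcript adds counts to low genes with many transcripts. Estimates of this kind divide reads between transcripts and genes that share exons, and that division can differ between libraries.

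The libraries held 42875143 (WT) and 55179026 (cKO) estimated counts. Library sizes were scaled with TMM factors from edgeR 4.0.16 (R 4.3.3), which were 1.0006 for WT and 0.9994 for cKO. Levels were expressed as counts per 1000000 counts of the library (CPM), and the log2 ratio of cKO over WT was computed for each gene without a pseudocount. A gene was measured where the mean of the 2 libraries was at least 1 CPM. A count of 0 was set to a floor of 3 fragments (6 counts, or 0.14 CPM in WT and 0.11 CPM in cKO), and the resulting fold is a lower bound. Exact (Clopper-Pearson) 95% intervals of ratios were computed with scipy 1.17.1 under Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and, for figures, matplotlib 3.10.9. Shares of transcripts have 95% Wilson intervals, and the difference between Olig1 and Olig2 has a normal-approximation interval. These intervals and floors cover counting error only, since PCR copies are not independent molecules and differences between animals are not included. The bootstrap interval of a difference between list medians is a spread over genes.

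No significance test was run and no p-value computed for any gene or list, because 1 library per group leaves no residual degrees of freedom. Genes were counted by a rule of size, at least 1.5-fold with an interval that leaves out a ratio of 1. A total of 34 gene lists (646 genes) were fixed before the data were examined, along with the rules and the main design. They comprised mature oligodendrocyte and myelin, newly formed oligodendrocyte, oligodendrocyte precursor, lineage transcription factor, selenoprotein, selenocysteine machinery, thyroid hormone axis, cholesterol synthesis, and sphingolipid and fatty acid synthesis genes. Cell type lists covered astrocytes, neurons in general, spinal interneurons, motor neurons, sensory ganglion neurons, microglia, endothelium and pericytes, Schwann cells, meninges and fibroblasts, ependyma, red blood cells, skeletal muscle, and cartilage and bone. The rest covered proliferation, Nrf2 and antioxidant, endoplasmic reticulum stress, p53 and apoptosis, immediate early, interferon response, Wnt, and Notch and BMP genes, both Hox lists, brainstem genes and sex-linked genes. Mitochondrially encoded and ribosomal protein genes were taken by symbol. Of the fixed genes, 2 were not found under their symbols in the files. Each list's median was placed among 10000 random lists of as many measured genes, drawn within 20 bins of mean level, and a percentile below 2.5 or above 97.5 was called standing apart. This percentile describes these 2 libraries only.

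Named genes followed a fixed rule: Secisbp2l, the measured selenoproteins, from each list up to 6 members of largest ratio past the size rule and up to 3 of highest level, and the 12 highest and 12 lowest ratios among genes of at least 5 CPM past the rule. Transcripts of Secisbp2l, Mbp, Mag and Nfasc with at least 10% of the gene's counts were also named. Some results for genes that the rule takes are not reported here. Gene positions, exons and overlaps came from GENCODE M21 on GRCm38, which held 99.6% of the identifiers and gave the same start and end for 93.8% of the genes. Of the 179 genes taken by the rule, 24 share exons with another gene on their strand, and for these the summed ratio is given where it differs. Of the same genes, 46 overlap an exon of an antisense gene with counts; as the strand setting is not given, their counts may hold antisense reads.

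The procedure was tested on simulated data with 200 changed genes at the depths and levels of the 2 libraries. Of genes changed 1.5-fold, 57.5% of 80 were called with the right direction, with 91.7% of 60 at 2-fold and 98.3% of 60 at 4-fold. Of 15707 unchanged genes, 0.48% were called, and of the 12536 at 5 CPM or more 0.02%. Intervals held the true ratio for 95.6% of 15932 genes. This simulation has counting error only and no variation between animals. Alternatives were total counts, DESeq2 1.42.0 size factors, upper quartile scaling, TMM without myelin, mitochondrial, haemoglobin and ribosomal genes, other filters and fold limits, the authors' TPM with pseudocounts of 0.1 and 1, transcript counts summed per gene, other random lists, and means in place of medians. Alternatives added after the data had been seen were intervals on counts as deposited, autosomal genes only, overlapping genes summed, and overlapping genes and pseudogenes left out. FPKM values deposited by the authors served only for the check of how counts were made.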

Results

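Spinal cord RNA was sequenced from C57BL/6 mice at postnatal day 7, when oligodendrocytes of the cord are forming myelin. The data comprised 1 library from wild-type mice (WT) and 1 library from mice carrying Olig1-Cre and a Secisbp2l allele floxed at exon 3 (cKO). Olig1-Cre drives recombination in the oligodendrocyte lineage, and Secisbp2l encodes a relative of SECISBP2, the protein that binds the selenocysteine insertion element of selenoprotein mRNAs. The comparison asked how the transcriptome of the whole cord differed when Secisbp2l was targeted in that lineage. The labels do not say how many animals went into a library. With 1 library per group there was no replicate check of any difference, so no p-values are given. Intervals of a gene's or transcript's ratio below are 95% exact (Clopper-Pearson) intervals that cover counting error only. Other kinds of interval are named where they are given.

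The WT library held 42875143 estimated counts and the cKO library 55179026, with about 2 counts to a sequenced fragment. Counts above 0 were listed for 28316 genes in WT and 29659 in cKO. Mitochondrially encoded genes took 5.99% of the counts in WT and 5.57% in cKO, and the 10 most abundant genes took 6.21% and 5.35%. The 50 genes of the mature oligodendrocyte and myelin list took 2.19% of the counts in WT and 1.12% in cKO. The libraries also differed in the sex-linked genes. Xist, the RNA that silences an X chromosome in female cells, had 35182 counts in WT and 13 in cKO. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in WT and between 1081 and 4280 in cKO. Genotype and this sex-linked expression therefore differed together in every comparison below.

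The targeted gene was examined first. Secisbp2l (ENSMUSG00000035093) lies on the minus strand of chromosome 2, at 125736986 to 125782870 in GRCm38. It had 588 CPM on TMM-scaled library sizes in WT and 466 CPM in cKO, a log2 ratio of cKO over WT of -0.34 (interval -0.37 to -0.30), or 1.26-fold lower in the cKO library. Transcript Secisbp2l-201, of 18 exons and 6797 nt, held 99.5% of the gene's counts in WT and 99.2% in cKO, and its log2 ratio was -0.34. In the GENCODE M21 annotation its exon 3 spans 125773176 to 125773500, 325 bp that are all coding and leave a remainder of 1 when divided by 3. This exon makes up 4.78% of the transcript. The deposited values estimate whole transcripts and do not isolate exon 3, so they do not check its deletion. They also pool the cells in which Olig1-Cre acts with all the other cells of the cord.

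Across the transcriptome, 15917 genes were measured at a mean of at least 1 CPM. Most were close between the libraries, with a median log2 ratio of 0.01, quartiles of -0.14 and 0.15. A rule of size (at least 1.5-fold, with an interval that leaves out a ratio of 1) was met by 391 genes higher in the cKO library, 2.46% of those measured, and by 539 genes lower, 3.39%. At 2-fold or more, 130 genes were higher and 183 lower. Some genes named below as past the rule missed its 1.5-fold limit on the authors' TPM. With a pseudocount of 0.1 these were Sox10, Nkx2-2, Siglech, Ly6c1, Drp2, Ogn and Znrf3, and with a pseudocount of 1 Cnksr3, Isl2, Tnnt3, Matn3, Sp7, Pmaip1, Ifit1, Rsad2 and Smad7 missed it as well. Of the 179 genes that the naming rule takes, 46 overlap exons of an antisense gene with counts, among them Bcas1, Gpr17, Nkx2-2, Cers2, Igf2, Hoxd3 and Gt(ROSA)26Sor, and their counts are uncertain to that extent because the strand setting is not given. In the plot of levels in both libraries, most genes of the myelin list lay below the diagonal.

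**Figure D1:**
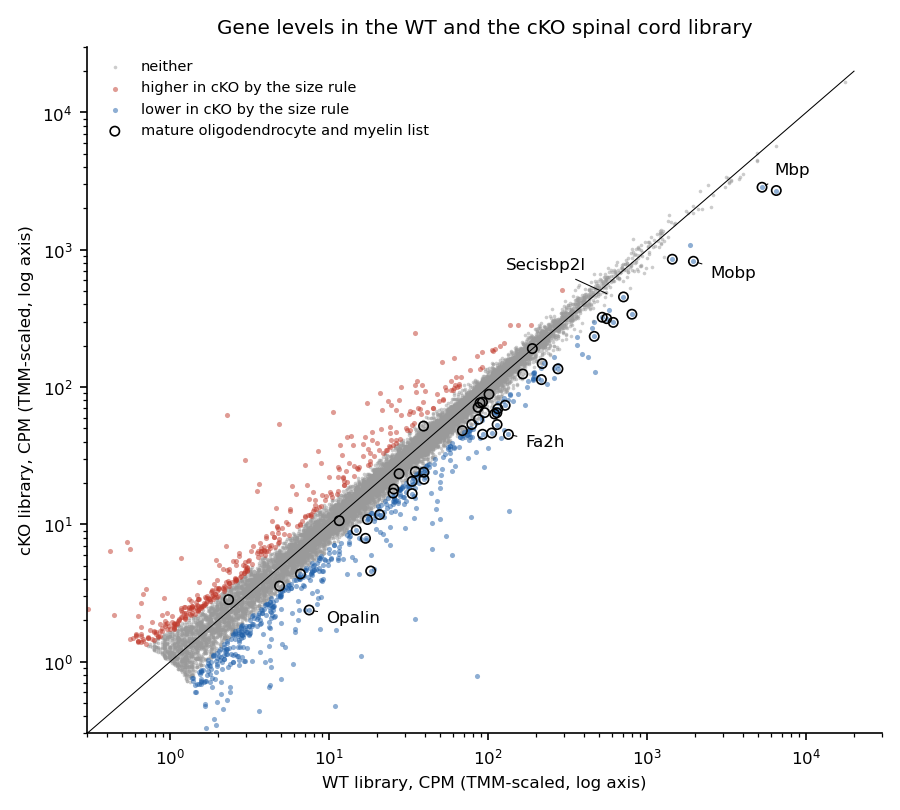
Level of each measured gene in the WT library (x axis) and the cKO library (y axis), in TMM-scaled CPM on log axes, with 1 library per axis and no error shown. Red and blue points are genes higher (391 in all) and lower (539 in all) by the size rule. Black circles are the 50 genes of the mature oligodendrocyte and myelin list, and the line marks equal levels. Genes at 0 in either library cannot be drawn on log axes. Genes below the lower end of an axis are cut off, among them Xist (0.24 CPM in cKO) and Rps3a3 (0.25 CPM in cKO).

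Genes of mature oligodendrocytes and myelin were lower in the cKO library. Of the 50 list members, 31 were lower by the size rule, 0 were higher, and 47 had a log2 ratio below 0. Mbp, which encodes myelin basic protein, stood at 5277 CPM in WT and 2854 CPM in cKO (log2 ratio -0.89, interval -0.90 to -0.87). Mobp, for another basic protein of myelin, had a log2 ratio of -1.25. Fa2h and Ugt8a, enzymes that make the hydroxylated and galactosylated sphingolipids of myelin, had ratios of -1.57 and -1.24. Opalin, a membrane protein gene of late oligodendrocytes, had -1.66 (interval -2.08 to -1.22) on 321 and 131 counts. Evi2a had the lowest ratio of the list, -1.996, or -1.76 when counts were summed with the genes that share its exons. The list's median log2 ratio was -0.71. The lowest median among 10000 random lists of as many genes matched on expression was -0.09, and no random list held more than 7 genes lower by the size rule. Of the 50 members 2 are X-linked.

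The main transcripts of Mbp, Mag and Nfasc were lower in parallel, with small shifts in their shares. Mbp-210 had a log2 ratio of -0.95 and held 42.5% of the Mbp counts in WT (Wilson interval 42.2% to 42.8%) and 40.8% in cKO (40.4% to 41.1%). Mbp-211 had -0.89 and held 38.0% and 37.8%. For Mag, an adhesion molecule of the myelin sheath, the log2 ratios were -0.58 for Mag-203, -0.68 for Mag-204 and -0.76 for Mag-207. Nfasc-202, the main transcript of neurofascin, which is found at nodes of Ranvier and in paranodal glia, had a log2 ratio of -0.51 and 83.5% and 83.0% of the gene's counts. These transcripts share most of their exons, so the division between them rests on the authors' estimate.

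Newly formed oligodendrocyte genes were lower by a smaller amount. Of 21 measured members, 6 were lower by the size rule, 0 were higher and 20 lay below a log2 ratio of 0, with a median of -0.38 against a lowest random median of -0.16. Those 6 were Neu4 (-1.09), Bcas1 (-0.84), Bmp4 (-0.78), Enpp6 (-0.76), Gpr17 (-0.64) and Cnksr3 (-0.63). Bcas1 and Enpp6 are markers of cells that have just begun to differentiate, and Gpr17 is a receptor of committed precursors. Sirt2, at -0.58, missed the 1.5-fold limit.

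Precursor genes differed little. All 24 members of the oligodendrocyte precursor list lay within 1.5-fold, between -0.32 and 0.19, and 0 met the size rule in either direction. Below a log2 ratio of 0 lay 17 of the 24. The 3 most abundant members, Cspg5, Ednrb and Ncald, had ratios of 0.19, 0.14 and 0.08. The precursor markers Pdgfra, Cspg4 and Lhfpl3, chosen after their values were seen, had ratios of -0.07, -0.145 and -0.27. The median of -0.06 lay at percentile 3.32 of random lists, inside the central 95% that a list had to leave to stand apart. With random lists also matched on gene length it lay at percentile 2.07, and with autosomal genes only at 2.27, both outside that range. On the authors' TPM the median was 0.01.

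Transcription factors of the lineage stood apart as a list, with a median of -0.22 against a lowest random median of -0.16. Of 20 members, 4 were lower by the size rule and 0 higher. Olig1, the gene for which the Cre line is named, stood at 388 CPM in WT and 175 CPM in cKO (log2 ratio -1.14, interval -1.20 to -1.09). Zfp488 (-0.75), Nkx2-2 (-0.63) and Sox10 (-0.59), which act in oligodendrocyte differentiation, were the other 3. Sox10 and Nkx2-2 lay close to the limit of the rule. Sox10 missed it with upper quartile scaling (-0.575), and on the authors' TPM with a pseudocount of 0.1 both did, Sox10 at -0.557 and Nkx2-2 at -0.569. Zeb2 was at -0.48.

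**Figure D2:**
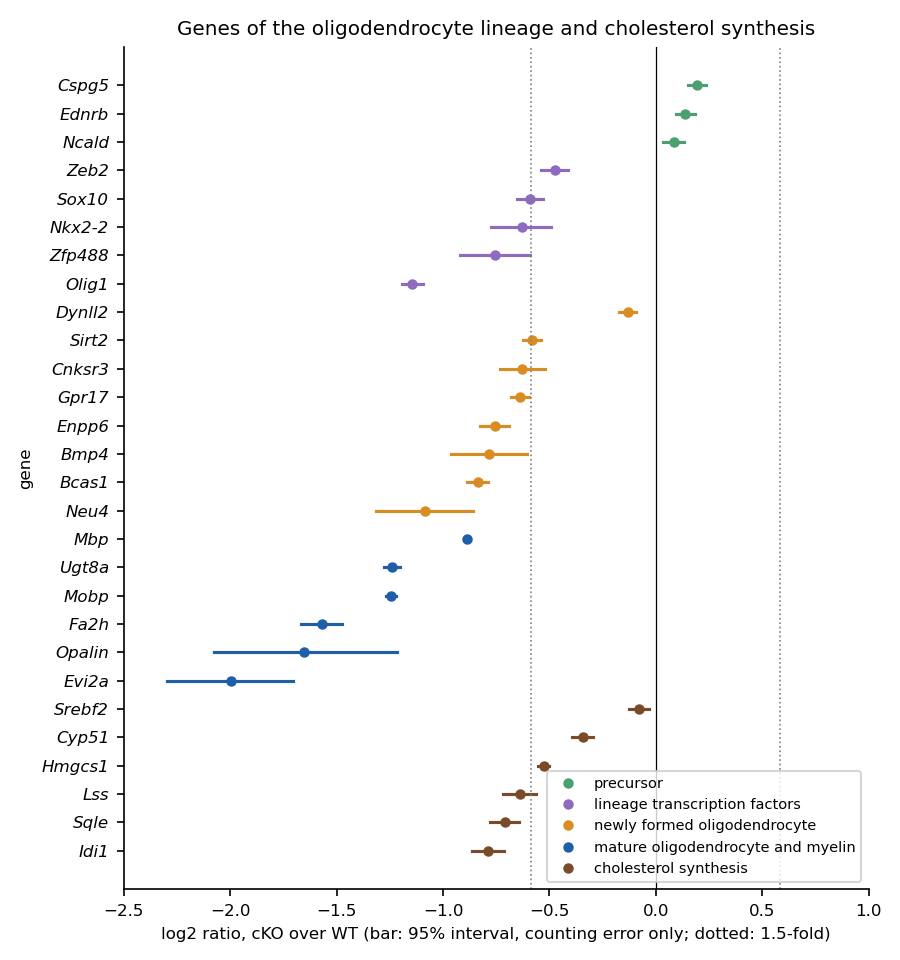
Log2 ratio of the cKO over the WT library for genes of 4 oligodendrocyte-lineage lists and of cholesterol synthesis, coloured by list. Points are ratios from 1 library per group, bars are 95% intervals of counting error only, and dotted lines mark 1.5-fold; only members picked by the naming rule are drawn, so the 3 precursor genes shown, between 0.08 and 0.19, do not stand for the list, which spans -0.32 to 0.19.

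Cholesterol synthesis genes were lower together. All 25 members had a log2 ratio below 0, 4 were lower by the size rule and 0 higher, and the median was -0.37 against a lowest random median of -0.14. Among the 4 were Idi1 (-0.79), Sqle (-0.71) and Lss (-0.64), which encode enzymes of the pathway. Hmgcs1, the most abundant member, went from 1279 CPM in WT to 888 CPM in cKO (-0.53). Srebf2, the transcription factor that controls the pathway, was at -0.08. The sphingolipid and fatty acid synthesis list had a median of -0.14, with 1 of 20 members lower by the rule and 0 higher. That member was Cers2 (-0.80), which makes the very long chain ceramides used in myelin. Scd2 and Fasn, abundant genes of fatty acid synthesis, were at -0.17 and -0.15.

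Selenoprotein mRNAs, which carry the element bound by SECISBP2, did not stand apart. These are mRNA levels of the whole cord, so they measure neither selenoprotein synthesis nor the targeted lineage alone. Of the 21 measured, 20 lay between -0.29 and 0.38. The median was -0.04 at percentile 13.14, while the mean was 0.07, of the opposite sign. Dio2, which activates thyroid hormone, was at 0.11 (interval -0.07 to 0.29). Gpx4 (-0.01), Txnrd1 (-0.02), Selenow (-0.04) and Sephs2 (0.00) were close to equality, while Selenof (-0.29) and Selenos (-0.27) were among the lowest and Selenoh (0.38) and Txnrd3 (0.31) among the highest of the 20. The exception was Selenoi, an enzyme of phosphatidylethanolamine synthesis, which stood at 20.8 CPM in WT and 90.7 CPM in cKO (2.13, interval 1.98 to 2.28). Transcript Selenoi-203, looked up after this value was seen, held 775 of the gene's 890 counts in WT and 4813 of 5003 in cKO by the authors' estimate. Of the 16 selenocysteine machinery genes, 0 met the size rule, with a median of 0.03 at percentile 57.04. Thyroid hormone axis genes had a median of 0.01 at percentile 49.05, and 0 of 19 met the rule. Thra, the most abundant, was at -0.02.

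Other cell types of the cord differed by smaller amounts. General neuron genes had a median of 0.17 (percentile 99.88; 20 of 22 above 0) and spinal interneuron genes one of 0.21 (percentile 100; 21 of 22 above 0), yet 0 members of either list met the size rule. Nefm, a neurofilament gene, was at 0.26, and Slc6a5, the glycine transporter of inhibitory neurons, at 0.30. Motor neuron genes had a median of 0.03 (percentile 66.67), with Isl2 higher by the rule on 76 and 153 counts and Ret at 0.21. Astrocyte genes had a median of -0.05 (percentile 1.46), 0 of 22 met the rule, and Gfap was at -0.07; the list lay inside the central 95% when random lists were also matched on length (percentile 4.37). Microglia genes (-0.07, percentile 13.87, 1 of 22 lower), endothelial and pericyte genes (0.08, percentile 92.86, 1 of 23 lower) and ependymal genes (-0.13, percentile 16.46, 1 of 14 lower) did not stand apart. The single genes lower by the rule there were Siglech, Ly6c1 and Mia. Mia shares exons with other genes, and its summed locus had a ratio of -0.30. Proliferation genes had a median of -0.01 (percentile 47.12) and 0 of 25 met the rule.

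Tissues next to the cord were also compared. Schwann cell genes had a median of -0.10 (percentile 7.64), with 8 of 15 below 0. Pmp22 and Prx, genes of peripheral myelin, were at 0.13 and 0.40, and Drp2 was the only member of that list lower by the rule (-0.81), a call lost on the authors' TPM with a pseudocount of 0.1 (-0.462) or 1 (-0.441). Meninges and fibroblast genes had a median of -0.13 (percentile 0.24), and 2 of 18 were lower, Igf2 (469 CPM in WT and 129 CPM in cKO, -1.87) and Ogn (-0.60, or -0.578 with upper quartile scaling, short of the limit). The collagen genes Col1a1 and Col1a2 were at -0.11 and -0.14. Cartilage and bone genes had a median of -0.53, and 5 of 11 were lower by the rule: Comp, Matn3, Cnmd, Sp7 and Runx2, each with 245 counts or fewer in a library. With a filter of 5 CPM the list's median was -0.09 at percentile 17.43. Red blood cell genes had a median of 0.47, and Hbb-bs stood at 465 CPM in WT and 671 CPM in cKO (0.53). Haemoglobin genes took 0.13% of the counts in WT and 0.19% in cKO. Sensory ganglion genes (5 measured, 0.10, percentile 77.33), skeletal muscle genes (3 measured, 0.20, percentile 82.23; mean of -0.13) and brainstem genes (7 measured, -0.12, percentile 16.36) did not stand apart, with 1 gene past the rule, Tnnt3 of muscle, at -0.84.

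Signalling and stress lists gave few genes past the rule. The Nrf2 and antioxidant list had a median of -0.07 (percentile 2.23) with Ftl1, the ferritin light chain gene, lower (-0.74, or -0.89 summed with Gm22133, which shares its exon), but lay inside the central 95% with random lists matched on length (percentile 7.20). Medians were -0.07 for endoplasmic reticulum stress (percentile 7.60, 0 of 18), -0.04 for p53 and apoptosis genes (percentile 22.28, Pmaip1 lower, 1 of 15) and 0.09 for immediate early genes (percentile 89.27, 0 of 14). Interferon response genes had a median of 0.17 (percentile 98) with Ifit1 (1.12) and Rsad2 (0.77) higher on 210 counts or fewer, and a median of -0.05 under the filter of 5 CPM. The interferon list no longer stood apart on the authors' TPM with a pseudocount of 0.1 (percentile 88.24) or by its mean (95.41). Wnt signalling genes had a median of 0.10 (percentile 89.39, or 98.73 on the authors' TPM with a pseudocount of 0.1) with Znrf3 higher (0.65), and Notch and BMP genes one of 0.01 (percentile 55.60) with Smad7 lower (-0.72). Mitochondrially encoded genes (-0.13, percentile 0.12, 0 of 13 past the rule) and cytosolic ribosomal protein genes (-0.09, percentile 0.00, 1 of 77 lower) stood apart by small shifts. The mitochondrial list lay inside the central 95% with unmatched random lists (percentile 3.25) and by its mean (4.19), and the ribosomal list by its mean (2.85). Of the 35 list medians, 15 stood apart, where 5% of independent lists would make 1.8. Random lists take genes that need not vary together, so small shifts of co-regulated genes reach extreme percentiles.

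Hox genes, whose paralogue groups follow position along the cord, were compared as 2 lists. Of the 12 measured members of the thoracic to lumbosacral list, 3 were higher by the rule (at most 3 in any of the 10000 random lists): Hoxd10 (1.65, interval 1.18 to 2.13), Hoxc10 (0.85) and Hoxd9 (0.73). Hoxd10 and Hoxc10 share exons with neighbouring genes, and the summed loci had ratios of 1.65 and 0.76. The list's median was 0.11 at percentile 93.94, inside the central 95%. It lay outside with random lists also matched on length (percentile 98.05), as did the mean of 0.33 (percentile 99.57). The cervical and brachial list had a median of 0.09 (percentile 89.93, mean of -0.02) and 1 of 14 members lower, Hoxd3 (-0.97, or -0.46 for the summed locus).

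**Figure D3:**
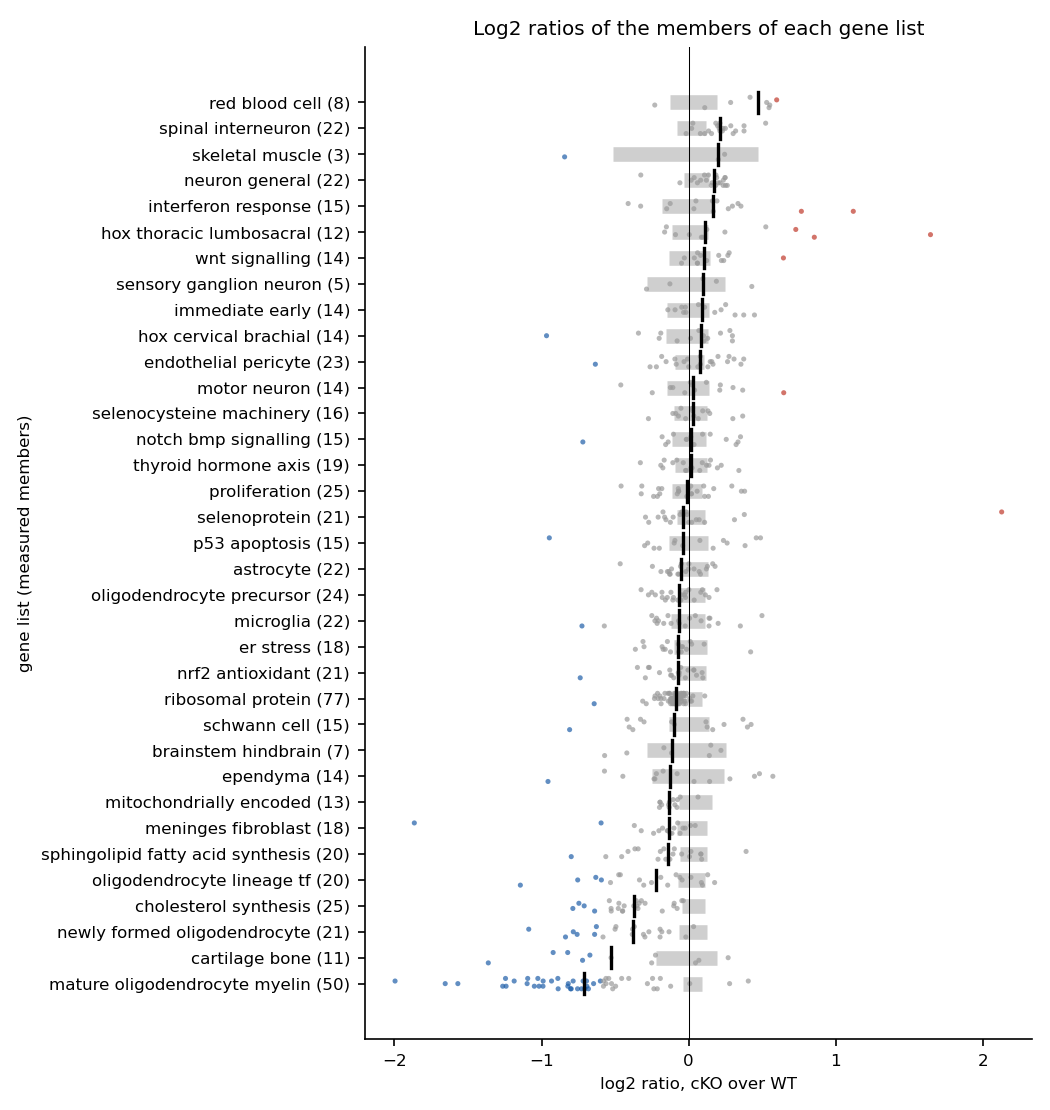
Log2 ratio of the cKO over the WT library for each measured member of the 35 lists (points; red higher, blue lower, grey neither by the size rule; vertical scatter only separates points). Black ticks are list medians and grey bars span the central 95% of medians of 10000 expression-matched random lists; the mature oligodendrocyte and myelin list has the lowest median, -0.71.

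The genes of at least 5 CPM with the most extreme ratios were mainly sex-linked genes and genes whose counts were hard to separate from those of a neighbour. Apart from Xist and the 4 Y-linked genes, 8 of the remaining 19 share exons with another gene on their strand in the GENCODE M21 annotation. Pcdhgc3 (-3.45), Pcdhga9 (-2.78) and Pcdhgb8 (4.77) belong to the gamma protocadherin cluster, whose 41 overlapping genes had a summed log2 ratio of 0.02. The ratios of Gm22133 (-11.41, on 1 count in cKO, interval reaching up to -8.53), Gm11226 (-4.53), Adat3 (-4.09) and Gm21982 (8.89, on 2 counts in WT, interval 6.41 to 14.20) became -0.89, 0.14, -0.24 and 0.15 for the summed loci. Rnf26 kept a summed ratio of 1.72. Rps3a2 and Rps3a3 (-6.78 and -6.96) are processed copies of the ribosomal protein gene Rps3a1, and the 3 copies summed to -0.10. Zbtb9 (-3.85) and Ggnbp1 (2.43) overlap on the same strand by their deposited positions and summed to 0.08. The genes without such a neighbour on their strand were Gt(ROSA)26Sor (-3.30), Lrrc8d (-2.75) and Tead1 (-2.73) among those lower, and Arl5b (3.49), Sesn3 (2.84), Kcnd3 (2.63) and Fam109a (2.31) among those higher. On the authors' TPM with a pseudocount of 0.1, Arl5b was at 2.301 and Tead1 at -1.893, and with a pseudocount of 1 at 2.067 and -1.675. Sesn3 encodes a stress-responsive regulator of growth signalling and stood at 34.5 CPM in WT and 247 CPM in cKO. Transcripts of Sesn3 and Arl5b were looked up after these values were seen. Sesn3-204 held 1415 of the gene's 1478 counts in WT and 13485 of 13610 in cKO. Arl5b-202 held 137 of 206 counts in WT and 2897 of 2979 in cKO. In the deposited estimates, the higher counts of Sesn3 and Arl5b thus lay mainly in these transcripts. The division between transcripts rests on the authors' estimate. Tead1 encodes a transcription factor of the Hippo pathway.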

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

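All the checks in this part, which carry no p-value, were chosen after the results had been seen. The Y-linked genes were outside the comparisons of gene groups and showed a signal in the cKO library above the WT library, where each had 0 counts. Ddx3y had 4280 counts in cKO, Eif2s3y 2116, Kdm5d 1534 and Uty 1081. Against the floor of 6 counts these were at least 555-fold, 274-fold, 199-fold and 140-fold higher. Xist was 3479-fold higher in WT. These are the counts of female tissue in the WT library and of male tissue in the cKO library. Neither library has a partner of its own genotype and the other sex, so effects of sex and of genotype on autosomal genes cannot be told apart.

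For the lower myelin genes, the list's own X-linked members were left out as a check. The 48 autosomal members had a median of -0.70. With only 2 of the 50 members X-linked, leaving them out could hardly move the median. Dosage of those 2 genes therefore does not set the list's median. The check cannot address X-linked genes that act on autosomal myelin genes. A loss of oligodendrocyte-lineage cells of every stage alike was not decided. The precursor list's median was higher than the myelin list's by 0.65 on the log2 scale (bootstrap interval over genes 0.51 to 0.78). Such a loss would lower both lists alike only if other cells of the cord expressed neither, which was not tested. In the whole cord, precursor genes were thus lowered less than myelin genes. Sex acting through autosomal genes stays open, with 1 library of each genotype and so no female cKO or male WT library to compare. A more caudal piece of cord in the cKO library also stays open: the 3 measured Hox genes of paralogue group 10 had a median log2 ratio of 0.85, and no WT tissue of known level was there to show how myelin genes vary along the cord. Fewer or less mature oligodendrocytes in the mutant is a hypothesis that was not tested. These 2 libraries do not separate it from sex, position or differences between animals. The labels give Olig1-Cre for the cKO library only. Any effect of the Cre allele on myelin genes therefore cannot be told apart from that of targeting Secisbp2l.

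Olig1 had a lower ratio than any other transcription factor of the lineage list, the next being -0.75. If Cre replaces 1 copy of Olig1, that loss may contribute. Olig1 lay below Olig2, its neighbour gene chosen after its values were seen, by a log2 difference of -0.61. The difference had a normal-approximation interval of -0.70 to -0.52, short of the -1 that loss of 1 of 2 copies would give at equal expression. Fewer or less mature oligodendrocyte-lineage cells may contribute as well, since 7 genes of the myelin and newly formed lists had lower ratios than Olig1. The labels do not state whether Olig1 is disrupted on the Cre allele, and neither value decides between the explanations.

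The very large folds at both ends of the ranking may in part come from counts allotted differently between genes that share exons. For the 8 named genes in such loci, the median absolute log2 ratio was 4.31 and became 0.14 when counts were summed over the locus. Summing with more abundant neighbours pulls a ratio towards equality whatever the cause, and Pcdhgc3, Pcdhga9 and Pcdhgb8 entered with the same summed locus. This fall therefore does not show by itself that counts were allotted differently. Among the 71 measured genes of 4-fold or more, 39.4% share exons with another gene, against 7.7% of genes under 1.5-fold. Of the other 11 genes, 4 stay open: Zbtb9 and Ggnbp1 overlap each other by their deposited positions, and Rps3a2 and Rps3a3 are processed copies of Rps3a1. The last 7 share no annotated exon on their strand and lie in the span of no measured gene on it. Exons shared on the strand therefore do not account for them. Their absolute ratios were at least 2.31 (at least 1.893 and 1.675 on the authors' TPM with pseudocounts of 0.1 and 1), but they were picked for extreme ratios. Exons of Gt(ROSA)26Sor, Lrrc8d and Kcnd3 overlap those of the antisense genes Thumpd3, Lrrc8dos and Kcnd3os, which have counts. As the strand setting is not given, antisense reads were not excluded there. No biological explanation was tested.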

How the results depend on the processing

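No paired analysis was possible because each group had 1 library. The scalings shifted the median of all genes by at most 0.02 on the log2 scale and the authors' TPM by 0.04. Summing transcript counts per gene could alter no value, since the gene counts are those sums. Values that an alternative cannot alter, such as this one, were left out. Of those that answer a comparison, 103 were kept, 16 moved and 2 newly stood apart. Kept meant the same sign and side of the limit for a list and a ratio inside its main interval for Secisbp2l. For a number of genes it meant within 1.5-fold of the main number. Among other lists and single genes 1441 were kept, 45 no longer passed their limit, 5 newly passed it and 4 reversed. There, a list that did not stand apart could change sign and still count as kept. The median of the myelin list ranged from -0.72 to -0.65, of the newly formed list from -0.38 to -0.33 and of cholesterol synthesis from -0.44 to -0.33. Higher and lower genes, whose counts follow the limits by construction, numbered 190 and 306 with a filter of 5 CPM, 657 and 826 with no filter, 130 and 183 at 2-fold, 990 and 1244 at the lower fold limit that was tried, and 137 and 241 with the interval wholly beyond 1.5-fold. On the authors' TPM they numbered 532 and 519 with a pseudocount of 0.1, and 327 and 354 with a pseudocount of 1; the cause was not tested. On TPM the Secisbp2l ratio was -0.283 (pseudocount 0.1) and -0.281 (pseudocount 1), and the precursor median was 0.007 with either, at percentiles 13.52 and 13.44; the cause was not tested. The precursor median of -0.063 moved to percentile 2.07 with random lists matched on length, and with autosomal genes only it was -0.074 at percentile 2.27; the cause was not tested. The mean of the selenoproteins was 0.067, set by Selenoi. Interferon response genes reversed to -0.045 with the filter of 5 CPM, which leaves out the low members. With overlapping genes summed, Gm11226 reversed to 0.140, and Pcdhgc3 and Pcdhga9 to 0.019. Among the unchanged genes of the simulated data, 0.48% were called, and 0.02% of those at 5 CPM or more, so chance calls by counting error lay mainly among low genes.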

Other observations

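The check in this part, which carries no p-value, was chosen after the results had been seen. The ratio of the Hox genes followed their paralogue number. Across the 26 measured Hox genes, which are not independent replicates, Spearman's rho between paralogue group and log2 ratio was 0.49 and Pearson's r 0.55. Without paralogue groups 9 and above, rho over the remaining 19 genes was 0.18, so the relation rests mainly on the caudal genes. Hoxa10, outside the rule for named genes and chosen after its values were seen, had a log2 ratio of 0.53. A larger share of caudal cord in the cKO library is a candidate explanation, with the median of 0.85 for paralogue group 10, but a difference between animals in the level of these genes was not separated from it.

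Igf2, of imprinted expression, was 3.64-fold lower in the cKO library while Col1a1 and Col1a2 of the same list were at -0.11 and -0.14. Gt(ROSA)26Sor, a locus widely used to insert transgenes, was 9.82-fold lower in the cKO library, and the labels name no insertion there; its exons overlap those of the antisense gene Thumpd3.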
